A study of Drosophila melanogaster with 6 samples.

How the data were processed

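GAGA factor (GAF), the product of the Trl gene, is a DNA-binding protein that recognises GA-rich sequence. Per the labels, its binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in 8 to 16 h embryos of the y cn bw sp strain, cross-linked in 1.8% formaldehyde for 15 min. The antibody was a rabbit polyclonal against part of GAF. The 6 libraries were 3 of GAF ChIP DNA and 3 of input DNA, which is chromatin DNA sequenced without immunoprecipitation.

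The authors deposited 1 peak list for the whole series, with a position and a score for each peak. Per the submitters' processing notes the tools were CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2, with genome build BDGP5, and per the file headers the coordinates are on FlyBase release 5. The deposited score is the authors' value for each peak, given as a positive number; its scale or transformation, the calling threshold and the way the libraries were combined are not given in the sources used here. The score was used to describe, rank and filter peaks within this list. No value per library was used, so there was no replicate spread, no test of ChIP against input, and no depth per library. The depth is unknown, and the confidence intervals given cover counting error only. Positions are written counted from 1, since the smallest listed start was 0. No column of per-sample values was left unmatched.

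Peaks were divided by sequence into the chromosome arms 2L, 2R, 3L, 3R, 4 and X, the heterochromatic scaffolds, the unplaced sequences U and Uextra, and the mitochondrial genome. The number of peaks per arm was compared with the arm's share of the summed spans by an exact two-sided binomial test with Benjamini-Hochberg adjustment over 6 arms. The span runs from the first to the last peak of an arm. It stood in for the arm length, which needed a genome of release 5 that was not used here, and it was chosen after the data were examined. Clustering was measured as the median distance between midpoints of neighbouring peaks and as the number of 100 kb windows with 10 or more peaks. Both were compared with 1000 random placements of the same widths within each span with gaps of at least 51 bp, by a one-sided permutation test. Median score and width of each arm were compared with those of the other arms by a two-sided permutation test with 100000 resamples, adjusted together. Peaks are not independent replicates, so 100 kb windows were also permuted among arms.

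Even spacing, the relation of width to score, the comparisons of sequences outside the arms and the comparisons of the highest scores between arms were chosen after the data were examined. Even spacing was searched as the lowest coefficient of variation (CV) over runs of 10 spacings between peaks with a score of 100 or more, against 1000 shuffles of the spacings within each arm and 1000 random placements. The region around the best run was extended while spacings stayed below 3 times the mean of the run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

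The tests were run on 100 simulated lists of the 7429 arm peaks. The planted changes were clustering of 25% of the peaks, doubled scores on 3R and the loss of 25% of the peaks of X. For even spacing, 21 peaks were planted 5000 bp apart with an SD of 200 bp. Each change was recovered in 100 of 100 lists. With nothing planted, a call was made in 5 lists for clustering, 5 for medians, 2 for even spacing and 3 for density over permuted windows. Peaks in these lists were placed at random, uniformly for the density test, with no clustering beyond that planted. The recoveries and calls therefore do not show how the tests behave on clustered peaks. No arm difference was planted on chromosome 4, which has 100 peaks, so the recoveries do not show whether a similar change there would be called. For clustering, the lists were placed in the same way as the reference of the test. For medians, scores and widths were shuffled over the arm peaks, as the test itself assumes. The random positions likewise met the assumptions of the spacing and density tests. Few calls were therefore built in for all of these tests.

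The following analyses, fixed before the data were examined, were not run, because they need a genome or annotation of release 5: the share of peaks at promoters, the share with GAGAG, the relation of score to the number of GAGAG, and the 22 gene lists. The gene table used was of release 6, assembly Release 6 plus ISO1 MT, so it served only for names and the order of genes, and no coordinate was taken from it. The rule for named items gave, without an annotation of the same build, the 20 peaks with the highest score and the 5 densest 100 kb windows, as regions. The alternatives were the 5857 peaks at or above the median score, joining of peaks under 500 bp apart, arms only, removal of the 1% highest scores and 50 kb windows. Alternatives added after the data were examined were permuted windows (for the whole list, and for each alternative of density and the higher-scoring peaks of the medians), joining under 2000 bp, removal of the 2 densest windows with their length, other settings of the spacing search, and subsets of the width comparison.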

Results

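The list held 11713 GAF peaks on 15 sequences of FlyBase release 5, from 3 GAF ChIP and 3 input libraries of 8 to 16 h embryos. The chromosome arms carried 7429 peaks, 63.4% of the list (95% Wilson interval 62.5 to 64.3). Peaks covered 6128 kb of the arms. The authors' score ranged from 5.75 to 2174.57 with a median of 64.7 (quartiles 18.09 and 292.7). Widths ranged from 200 to 21540 bp with a median of 454 bp. No peaks overlapped, and the smallest distance between neighbours was 51 bp. With 1 list and no value per library, none of the values below has a replicate error.

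Arm peaks had a broad distribution of scores with many weak and many strong members. On the arms, 28.1% of peaks scored under 20 (27.1 to 29.1) and 29.0% scored 300 or more (28.0 to 30.0). Outside the arms, 26.4% scored under 20 (25.1 to 27.7) and 16.6% scored 300 or more (15.5 to 17.7). Wider peaks had higher scores, with a Spearman rho across the 11713 peaks of 0.795 (permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p over 4 sets 1e-05). Peaks are not independent replicates. Width and score also come from the same peak calls, so they are not separate measurements.

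**Figure D1:**
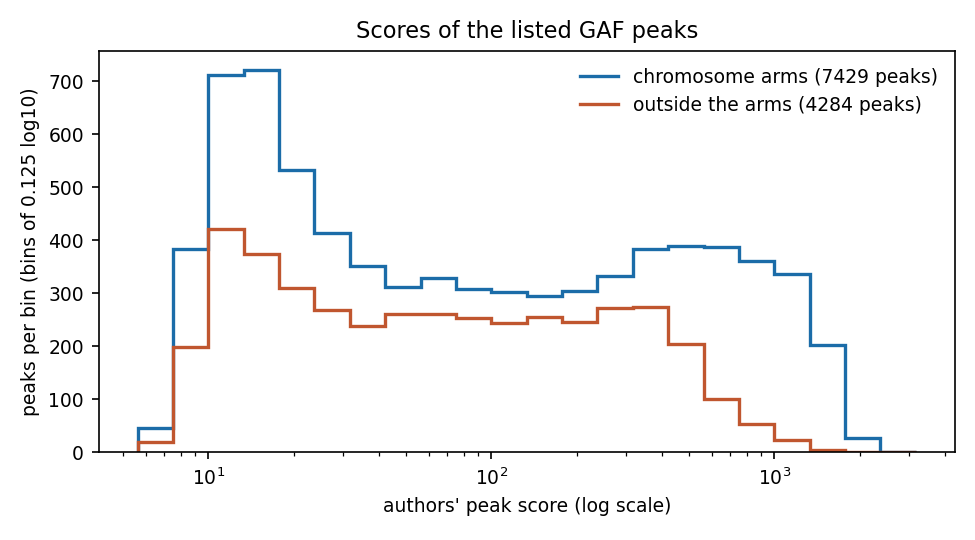
Number of peaks per bin of equal width on the log10 scale (vertical axis) against the authors' score on a log axis, for the 7429 peaks of the chromosome arms and the 4284 peaks outside them. The arm curve is highest from 10 to 17.8 and is lowest from 133 to 178 among the bins between 10 and 1000, with a second plateau from 316 to 750, and the other curve falls off above 422.

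The 20 strongest peaks lay on the large autosomal arms. Of the 20 peaks with the highest score, 7 lay on 2R, 5 on 2L, 4 on 3L and 4 on 3R, with 0 on X, 4 or outside the arms. In proportion to the whole list, 7.31 of them would fall outside the arms, and in proportion to the arm peaks, 3.69 would fall on X. The highest score, 2174.57, belonged to the 1556 bp peak on 2L from 14489818 to 14491373. It was followed by 2L 22018410 to 22020423 (score 2039.57), 2R 15993444 to 15995497 (2035.5) and 3L 14747306 to 14754198 (1990.84). Another of the 20, on 2R from 15997903 to 15999264 with a score of 1901.4, lay near the one on 2R. The remaining peaks of the 20 scored from 1832.23 to 1941.03. The highest score on X, 1810.48, was just under that range, so the absence of X depends on the cut at 20. The widest peak, on X from 3570321 to 3591860, was 21540 bp wide with a score of 1609.62.

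Peak density ranged from 58.9 to 76.8 peaks per Mb of span over the 6 arms. Per Mb of span there were 58.9 peaks on 2L, 65.6 on 2R, 64.0 on 3L, 58.9 on 3R, 76.8 on 4 and 61.2 on X. Chromosome 4, the small and largely heterochromatic autosome, had 1.24 times the share of peaks given by its span (95% interval 1.02 to 1.51), from 100 peaks. No arm passed the exact binomial test after adjustment, with adjusted p = 0.0657 for 4, 2R and 3R, 0.080 for 2L, 0.140 for 3L and 0.732 for X. With 100 kb windows permuted, the lowest adjusted p was 0.570. The binomial test takes clustered peaks as independent, and it called some arms under alternatives. Chromosome 4 passed among the 3796 arm peaks at or above the median score of the list (fold 1.53, adjusted p = 0.00741, exact binomial test). With joining under 500 bp, 2L passed (0.920). Without the 2 densest windows, 2L (0.903), 2R (1.08) and 4 (1.26) passed. With windows permuted under the same 3 settings no arm passed, the lowest adjusted p being 0.151 for 2L without the 2 densest windows and 0.188 for 4 among the higher-scoring peaks (permutation test).

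Median scores and widths did not differ between arms past the adjusted threshold in the whole list. The median score was 146.675 on 4 against 67.94 on the other arms, with a raw permutation p of 0.0137 and an adjusted p of 0.164 over 12 tests. The medians of the other arms ranged from 62.74 on 2L to 72.265 on X. Median widths ranged from 505 bp on X to 571 bp on 4. Among the peaks at or above the median score, the median on X was 328.44 against 383.74 on the other arms and that on 3R was 412.85 against 360.93, each with adjusted p = 0.0423 by the permutation test of peaks and 0.0766 with windows permuted. The difference on X thereby turned from 4.205 to -55.3, and that on 4 turned to -67.94.

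GAF peaks lay closer together than random placement gave. The median distance between neighbours was 5708.5 bp, against a mean of 11490 bp and a lowest value of 11098 bp in 1000 placements, a ratio of 0.497 (one-sided permutation p = 0.001, the smallest that 1000 placements can give). There were 230 windows of 100 kb with 10 or more peaks, against a mean of 104 and a highest of 126 in the placements. Joining peaks under 2000 bp apart, chosen after the data were examined, raised the ratio to 0.854. The number of dense windows fell to 101 with joining under 500 bp (highest placement 38) and to 8 with joining under 2000 bp (highest placement 7). It was 19 among the 3796 arm peaks at or above the median score of the list (highest placement 6). With windows of 50 kb it was 90 (highest placement 8).

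**Figure D2:**
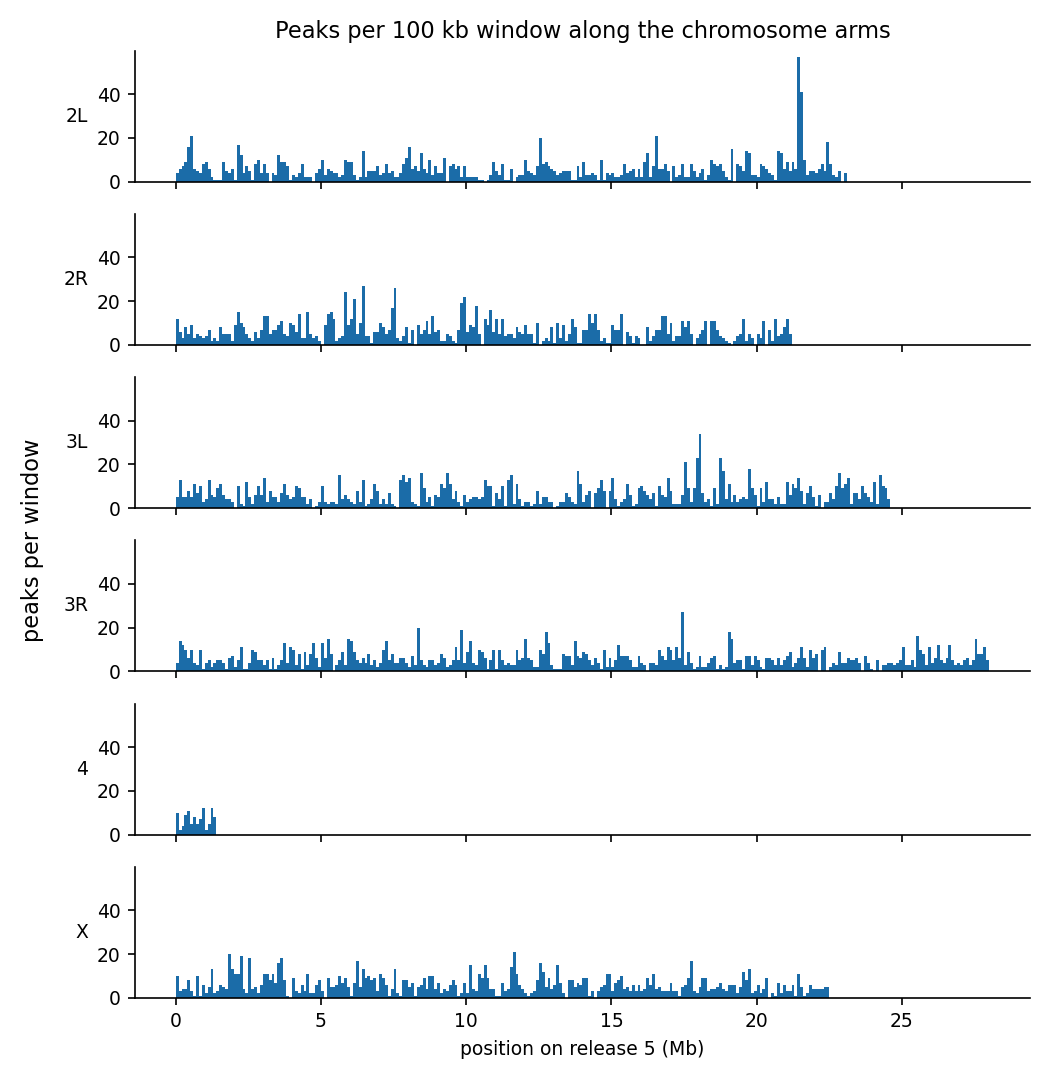
Number of peaks per 100 kb window (vertical axis) against position in Mb on release 5, for each chromosome arm. The 57 and 41 peaks in a pair of neighbouring windows of 2L stand above all others, the next being 34 on 3L.

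The densest windows were on 2L from 21400001 to 21500000 with 57 peaks and from 21500001 to 21600000 with 41, followed by 3L 18000001 to 18100000 with 34. The windows 2R 6400001 to 6500000 and 3R 17400001 to 17500000 held 27 peaks each. The median scores in these windows were 23.32, 26.17, 20.335, 44.05 and 83.37 in that order.

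Within the densest pair of windows, strong peaks recurred at a near-constant distance. From 21418250 to 21541861 on 2L, 23 peaks scored 100 or more (mean score 245 ± 47.7, SD over the 23 peaks) and 56 peaks scored less (median 20.47). Of the 22 spacings between the strong peaks, 21 averaged 5124 bp (SD 485 bp, range 4209 to 6715) and 1 was 14265.5 bp. The lowest CV over 10 spacings was 0.0514, against 0.306 elsewhere on the arms and lowest values of 0.221 in 1000 shuffles of the spacings and 0.113 in 1000 random placements (permutation p = 0.001 for each, the smallest possible). The region held 5.83% of the peaks of 2L. It was noticed before the test was chosen.

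**Figure D3:**
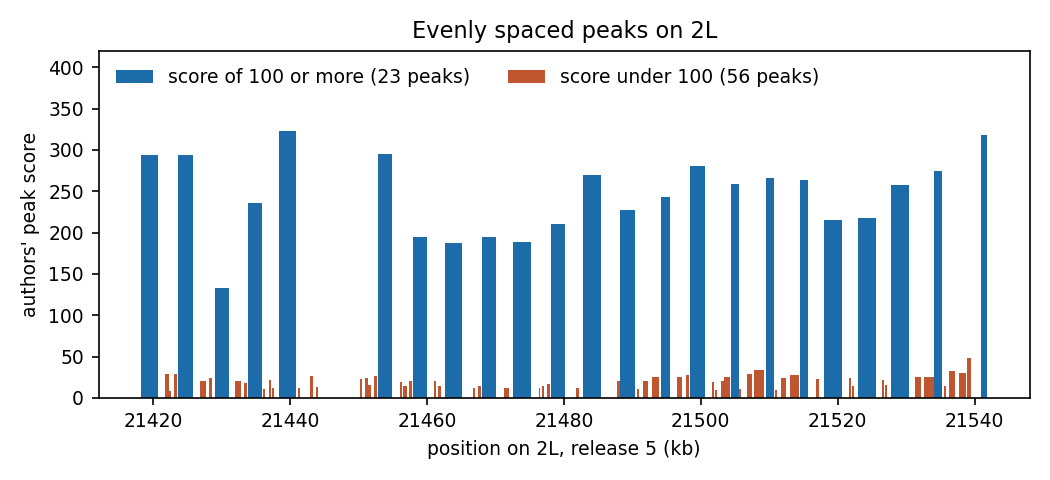
Authors' peak score (vertical axis) against position in kb on 2L of release 5, each bar as wide as its peak, for the 23 peaks with a score of 100 or more and the 56 weaker ones. The strong peaks repeat about every 5124 bp, apart from 1 spacing of 14265.5 bp.

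Peaks outside the arms numbered 4284, 36.6% of the list (35.7 to 37.5). Uextra, which collects unplaced sequence, held 3251 of them at 112 peaks per Mb of span, against 61.7 on the arms, 60.1 on the heterochromatic scaffolds and 48.1 on U. Single heterochromatic scaffolds ranged from 39.3 peaks per Mb on XHet (8 peaks) to 124 on 2LHet (44 peaks), above Uextra. Median widths were 390 bp on Uextra, 393 bp on U and 406 bp on the heterochromatic scaffolds, against 527 bp on the arms (adjusted p = 2e-05 each, permutation test). Uextra had a lower median score than the arms (54.89 against 68.86, adjusted p = 0.0013, permutation test). The scaffolds (65.78, adjusted p = 0.904) and U (69.9, adjusted p = 0.930) did not pass the permutation test. These comparisons were chosen after the data were examined. They take clustered peaks as independent, and no version with windows permuted was run for them.

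**Figure D4:**
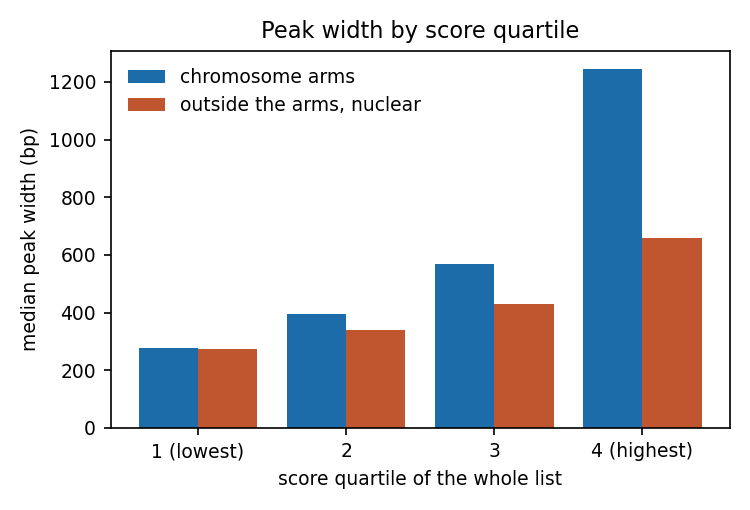
Median peak width in bp (vertical axis, from 0) by score quartile of the whole list, for the arms and for nuclear sequences outside them. The medians are 276 and 272 bp in the lowest quartile and 1246 and 657 bp in the highest.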

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

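All tests given here were chosen after the data were examined; the predictions of the width and repeat tests were written before their values were seen, the reading of a missed repeat prediction as evidence against it was settled after, and those of the test of weak calls and the comparison matched on score after. Peaks on sequences outside the comparisons by arm drew attention because they lie in data those comparisons do not use: 547 on heterochromatic scaffolds, 480 on U, 3251 on Uextra and 6 on the mitochondrial genome. The 6 mitochondrial peaks scored 126.73 to 200.28. They covered 96.8% of the 14928 bp from the first to the last of them, which is not the whole mitochondrial genome. The best-covered arm stretch of that length was covered to 100%. That maximum was fixed in advance by the 21540 bp peak on X and does not describe the arms in general, where peaks covered 6128 kb of 120.3 Mb of span. The cause of the mitochondrial coverage was not tested.

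The share of 36.6% outside the arms was weighed against technical explanations. Weak calls near the reporting limit are argued against, since 46.6% of the 4278 nuclear peaks outside the arms (1995; Wilson interval 45.1 to 48.1) scored above the median of the arm peaks. Narrowing by short contigs stays open: in the highest score quartile the median width was 0.527 of that on the arms (bootstrap interval 0.503 to 0.551), below the bound of 0.8, and 0.68 (0.647 to 0.717) with arm peaks matched on score, a smaller gap, so part of the difference came from higher arm scores. That test bears on the widths and not on how many peaks lie there. Equally shared reads between copies were to make repeats of score and width within 1% at least 3 times as frequent outside the arms. The ratio was 0.971, from 19.8 to 22.6% outside against 19.2 to 24.0% on the arms over 20 draws. That argues only against sharing that leaves copies alike within 1% at that excess. Copies differing by more than 1% in score or width do not enter the count, so shared reads in general stay open. No biological explanation was tested because the design names no second group of embryos.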

How the results depend on the processing

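The alternatives with permuted windows, without the 2 densest windows and with joining under 2000 bp, and all those of spacing and of width against score, were chosen after the data were examined. Over 23 results, 109 values under alternatives were computed. Of these, 84 kept direction and side of the threshold or, for a count of peaks, stayed within 1.5 times. Another 8 kept direction and passed the threshold only under the alternative. Direction turned in 15, 1 of them past the threshold, and 2 were counts that moved by over 1.5 times. The list fell to 5857 peaks at or above the median score and to 7429 on the arms, by construction. Density folds passing the test were, among the peaks at or above the median score, 1.53 on 4; with joining under 500 bp, 0.920 on 2L; and without the densest windows, 0.903 on 2L, 1.08 on 2R and 1.26 on 4. The fold on X, 0.991, turned to 1.00, 1.02 and 1.00 under these 3 settings and to 1.01, 1.03 and 1.00 with windows permuted as well, where no arm passed. Among the peaks at or above the median score, median scores differed by 51.92 on 3R and -55.3 on X and widths by 81 on 3R and -97.5 on X, all past the threshold with peaks permuted and none with windows permuted (adjusted p = 0.0766 each, permutation test). The score on X thereby turned from 4.205, and scores on 3L (4.155) and 4 (-67.94) and the width on 4 (-88) turned without passing. Without the 1% highest scores, the score difference on 2R turned to -1.26 from 0.045. The cause was not tested for any of these. The distance ratio stayed between 0.497 and 0.854 and passed in all 5 settings in which it was computed, and the lowest spacing CV stayed between 0.047 and 0.0645. No paired analysis was possible because the list carries no value per library, although ChIP and input share replicate numbers; for the same reason no replicate could be left out. Not run, for want of a genome or annotation of release 5 used here: every alternative for promoters, GAGAG, score against GAGAG and gene lists, arm length without gaps, gene number as denominator, and placement by distance to a transcription start. Depth is unknown, so the weakest detectable peak cannot be stated.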

Other observations

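Apart from the distance ratio and the number of dense windows of the whole list, the tests in this part were chosen after the data were examined. The bounds for phase, for joining under 2000 bp and for the 2 densest windows were written before their values were seen. Those for the spacing and the histone genes were written after. High scores on X were compared with those on the large autosomal arms because none of the 20 highest peaks lay on X, so the values below partly restate that. Of the 74 arm peaks in the highest 1% of scores, 5 lay on X where 13.7 were expected from its share (Fisher's exact test, odds ratio 0.317, adjusted p = 0.0377 over 6 arms), a test that includes those 20 peaks and takes clustered peaks as independent. Ratios of X to the large autosomal arms, taken at 4 percentiles of the score, were 0.908 at 75, 0.893 at 90, 0.882 at 95 and 0.926 at 99. At 95 the values were 1056 and 1198 (permutation of windows, p = 0.0137, not adjusted for the choice of percentile), but the bootstrap interval of the ratio, 0.818 to 1.00, reached past equality, so a lower level on X is not established. Chromosome 4 stood lower still at 95, with a ratio of 0.622 from 100 peaks, not tested.

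The evenly spaced peaks on 2L are a pattern noticed in the list and tested on the same list. Chance spacing is argued against, with a permutation p of 0.000999, the smallest that 1000 shuffles allow. A tandem repeat bound at the same weaker places in each copy was predicted to give the 56 weaker peaks a fixed phase. The resultant length was 0.484, under the 0.504 that 95% of random placements stayed under (permutation p = 0.0848), so the prediction was not met. A single harmonic can cancel when several sites lie in the same unit, and such a p does not show a random phase. The measure therefore cannot decide on such a repeat. Many strong peaks had a weaker peak ending shortly before them, for instance at 21423569 before 21423625 and at 21467932 before 21467990. Before the last strong peak, at 21540865, the nearest weaker peak ended at 21539460. Whether random placements give this as often was not tested. A candidate explanation is the histone gene array: the release 6 gene table holds 23 consecutive histone H3 genes on 2L, against 23 strong peaks at a score of 50 or 100 or more and 22 at 150 or more, and the longest run of another family on 2L has 17. Among the 22 spacings of the strong peaks, 1 was 14265.5 bp, against a mean of 5124 bp for the other 21, so equal counts do not pair each peak with 1 gene. The match was seen before it was tested, and other histone genes have runs of 23, 22 and 18. The position of the array on release 5 was not looked up, and no biological explanation was tested further.

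Closeness of peaks was weighed against 2 explanations. The array on 2L alone is argued against by the count of dense windows elsewhere, 228, above the highest of 127 in the placements; this follows from the 230 windows of the whole list, so leaving out 2 of them was no separate test. The distance ratio without them was 0.509. Broad bound regions listed as several peaks cannot be told apart from separate sites: joining under 2000 bp raised the distance ratio from 0.497 to 0.854, between the bounds of 0.8 and 0.9, with the observed 16470 bp still below the lowest placement of 18503 bp. Of 3633 arm peaks under the median score, 23.6% lay within 1000 bp of a stronger one, against 26.3% on average when scores were permuted within arms (two-sided permutation p = 2e-05), and window peak number and score had a Spearman rho of -0.144 across peaks. Permuting single scores over whole arms does not keep the local grouping of weak peaks, so this share does not bear on whether broad regions were split.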
